A study of Mus musculus with 3 samples.

How the data were processed

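RNA, surface protein and B cell receptor sequences were read from 1 pool of sorted splenic B cells of 3 female MRL/lpr mice aged 18 weeks. The cells were sorted as CD19 positive, T cell receptor beta negative and DAPI negative, and were then stained with 1 hashtag antibody per mouse and with antibodies against 10 surface proteins, per the labels' protocols. Droplets were made with a 10x Genomics kit that reads transcripts and receptor chains of the same cell. Cell Ranger 5.0.0, Seurat 4.0.0, R 3.4.3 and the mouse build mm10 are named in the submitters' processing notes, with no role or order. A further sample, receptor sequences of sorted naive cells, was not analysed here.

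The deposited matrix holds raw UMI counts of 31053 genes, 10 surface antibodies and 3 hashtags in 17658 barcodes, with no normalization by the authors that the files show. A deposited table lists 13970 cells with a cluster number, total counts and the percent of counts from mitochondrial genes, and its highest percent was 9.96. The name of its cluster column is the one that Seurat gives to clusters drawn from RNA and antibody counts jointly, at resolution 0.6. The contig table, deposited by the authors, gives the UMI count, gene calls and CDR3 of 32012 assembled receptor chains, of which 20831 were productive. Of the listed cells, 19 were absent from the matrix and 13951 were found in it, each with gene UMIs that summed to the value in the table.

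Each cell was assigned to the mouse of its highest hashtag where that count was at least 3 times the second, which left out 101 cells and kept 13850. The top hashtag held a median of 97.6% of a cell's hashtag counts. Of the 3707 barcodes outside the table, 1417 carried at least 30 counts of a second hashtag, and none of these barcodes entered a comparison between clusters or gates. No doublet caller was run: cells with 2 or more productive heavy chains or with UMIs above the 99th percentile of their cluster were left out in an alternative. Cells of other lineages were defined, after the data were seen, as cells with no UMI of 4 B cell genes or at least 5 UMIs of 17 myeloid and granulocyte genes, a share that grows with a cell's depth.

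The mice are the replicates, and cells are never counted as such. Gene UMIs were summed per cluster and mouse, and the sums of the same mouse are paired because they come from the same animal. Clusters were named from fixed marker lists. A marker counted as raised where its level was at least 10 CPM and at least 1.5 times that of the median cluster, and a cluster whose leading genes by fold contradicted a name, or which carried the markers of more than 1 class, kept its number only. Cluster 5 was an exception, made after these counts were seen: it carried 5 of 6 B1 markers beside 8 of 10 ABC markers and is called ABC-like because 2 of its 10 leading genes were ABC markers and 0 were B1 markers. The T cell gene Cd3g and the erythroid gene Hbb-bt were also among these leading genes. Without cells of other lineages Itgax was the only ABC marker left among them, so this ground for the name is weak. The table gives no class names, so the comparisons are between cluster numbers with a description added. Cluster 5 was compared with clusters 2, 1 and 8 as the design foresaw. Its comparison with cluster 4, which shares most of its markers, was chosen by cluster number after the markers had been seen. No cluster met the description of memory cells.

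Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, a quasi-likelihood fit with the mouse as a block, and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. One fit held all 30 sums of the 10 clusters, so that they shared 1 estimate of the spread, except that cluster 5 against cluster 4 was fitted on the 6 sums of these clusters. That comparison was first fitted on all 30 sums, with 303 genes past the threshold, and was changed to the 6 sums that the planned design asked for, with 53, after both counts had been seen. The standard error of a log2 change was taken as its size divided by the square root of the F statistic. CPM values are UMIs scaled to the total of a sum, with no TMM factor, and so the ratio of 2 CPM values can differ from the fitted change where a few genes take much of a sum. A second grouping used protein alone: cells above the crossing point of a 2-component Gaussian mixture for both CD11c and CD11b were set against cells below both and above that of CD23. The centred log ratios (log2, pseudocount 1) at these points were -0.895 for CD11c, 0.199 for CD11b and -0.352 for CD23. Of all cells 25.0%, 6.48% and 8.48% lay within 0.25 of them, and 41.3%, 14.9% and 32.5% lay above them. The CD11c gate was thus a loose one, since the mean of the plasmablast-like cluster 1, -0.818, also lay above it.

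Of 30 gene lists fixed in advance, the 29 with at least 3 measured genes were tested with camera from limma 3.58.1, at a preset correlation between genes of 0.01 and again with an estimated one. The genes named are, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 5 and the same direction in each mouse, up to 4 members of each list past the threshold by size, the genes of the antibodies, Tbx21 and Fas. Immunoglobulin, ribosomal protein and mitochondrial genes and models without a gene name were left out of the largest rises and falls, and some of these groups are described for some comparisons. Samples, lists, this rule and the planned tests and alternatives were fixed before the data were examined; the alternatives without other-lineage cells, without clusters 6 and 9, with all 10 clusters in the fit of cluster 5 against 4 and with at least 5 UMIs per chain were added later. Gene positions are those of the build mm10 (GRCm38).

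Antibody counts were turned into centred log ratios, averaged per cluster and mouse and compared with cluster 2 by limma, with the mouse as a block. Receptor shares were taken over cells with exactly 1 productive heavy chain. A clone was the cells of 1 mouse with the same heavy V and J genes, identical heavy CDR3 nucleotides and the same light V and J genes. Shares were compared over mice with an exact two-sided sign-flip test, whose smallest possible p with 3 mice is 0.25. V genes were counted once per clone, mouse and cluster and tested with edgeR where at least 10 clones used them. Shared clones were set beside 1000 permutations of the cluster labels among cells of expanded clones of the same mouse. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0 was used for the rest.

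The gene test for cluster 5 against 2 and for the gates, the surface protein test and the V gene test were run on simulated data with known changes. The comparisons with clusters 1, 8 and 4, the list tests, the sign-flip test and the clone permutation were not simulated. In the gene simulations the changed genes came only from those above a minimum expected count. Recovery of genes with few UMIs was thus not simulated. All other genes had the means of cluster 2, or of the CD23 gate, in both groups compared, with no difference between mice in these means. With the counts of cluster 5 against cluster 2, 91.0% of genes changed by 2 on the log2 scale, 67.2% of those changed by 1 and 15.2% of those changed by 0.5 were recovered among 10410 genes, and 2.52% of the calls were false. Over 10 further draws that comparison gave 0 to 4.65% false calls. With the protein gates 97.0%, 68.7% and 6.06% were recovered among 9721 genes, but 14.8% of the calls were false. The surface protein test recovered 3 of 3 shifted antibodies with 0 false calls. The V gene test recovered 0 of 9 genes changed by 4-fold with 0 false calls among 41 others, and, in an easier simulation written after that result, 3 of 3 genes changed by 6-fold with 3 false calls among 17 others. The alternatives were DESeq2 1.42.0, library size in place of TMM, no filter, no block, immunoglobulin genes left out, candidate doublets left out, only the clusters compared, other gates, clone definitions and UMI minimums, and each mouse left out in turn.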

Results

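Transcripts, 10 surface proteins and rearranged receptors were measured in the same splenic B cells of 3 MRL/lpr mice. MRL/lpr is an inbred mouse strain with a defective gene for the death receptor Fas, and it develops a disease that resembles lupus. Age-associated B cells (ABCs) are mature B cells that carry the integrins CD11c and CD11b and the transcription factor T-bet, and they accumulate with age and in autoimmune disease. The title of the series states that ABCs are heterogeneous, and there was 1 condition, so cells were compared with other cells of the same mice. Mouse 1 gave 3506 cells with 41088109 gene UMIs, mouse 2 gave 5834 cells with 51411398 and mouse 3 gave 4510 cells with 39437440. The median cell held 8957.5, 5251.5 and 5018 UMIs in mice 1, 2 and 3.

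The sorted cells fell into 10 clusters. Cluster 1 carried all 11 plasmablast markers, cluster 0 carried 6 of 9 marginal zone markers, cluster 2 carried 6 of 8 follicular markers and cluster 5 carried 8 of 10 ABC markers together with 5 of 6 B1 cell markers. Clusters 1, 0, 2 and 5 held 20.3% ± 8.71, 19.0% ± 9.57, 17.3% ± 8.77 and 7.14% ± 2.25 of the sorted cells (SD, n = 3 mice). Cluster 8 carried 8 of 9 germinal centre markers and all 15 proliferation genes and held 3.48% ± 2.29. Cluster 7, at 3.45% ± 1.22, carried all 15 proliferation genes and 10 of 11 plasmablast markers. Cluster 4, at 11.3% ± 5.60, carried all 10 ABC markers, 8 of 11 plasmablast markers and 9 of 15 proliferation genes, and it was left unnamed. Its leading genes by fold included Prss34, Mcpt8, Elane and Lyz2, which belong to granulocytes and macrophages. Without the 6.77% of its cells counted as other lineages, immunoglobulin V genes, Apoe and Itgb1 led. Prss34, Mcpt8, Elane and Lyz2 are among the genes that define other-lineage cells, so their loss from the leading genes was largely fixed by that filter. Cluster 6, at 4.08% ± 0.581, carried 6 ABC and 5 follicular markers. Cluster 3, at 11.9% ± 1.97, carried 6 marginal zone and 6 follicular markers, and cluster 9, at 2.05% ± 1.47, or 1.21% without mouse 1, carried 11 plasmablast markers with macrophage genes. The clusters appear, from the name of their column, to have been drawn from the same RNA and protein counts, so differences between them in these genes and proteins are partly built in, and the sort sets which cells the shares are taken over.

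**Figure D1:**
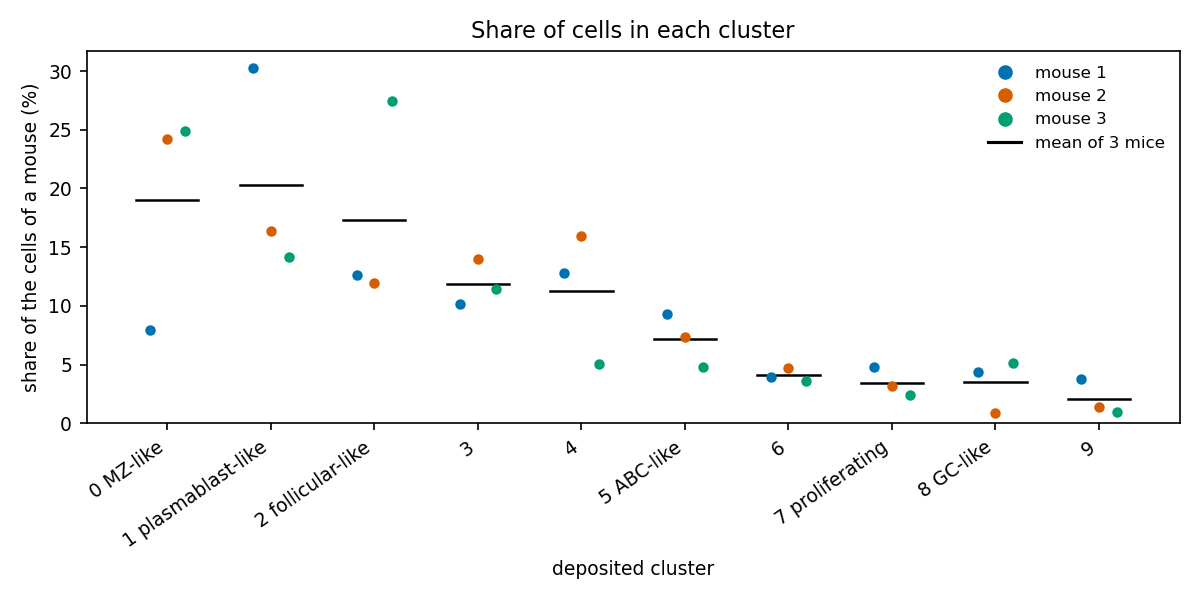
Share of the analysed cells of each mouse in each of the 10 clusters, in percent; points are the 3 mice and lines their mean. Shares differed widely between mice, as in cluster 0, which held 7.96% of cells in mouse 1 and 24.9% in mouse 3.

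The first comparison asked what sets ABC-like cells (cluster 5) apart from follicular-like cells (cluster 2) of the same mice. Most of the fixed ABC markers were higher in the ABC-like cells, and most of the follicular markers were lower. Itgax, the gene of CD11c on chromosome 7 from 128129547 to 128150657 (mm10), was higher by 4.86 ± 0.48 on the log2 scale (SE, n = 3 mice), at 73.2 ± 8.32 against 2.64 ± 1.47 CPM (SD). Fcer2a, the gene of the follicular IgE receptor CD23 on chromosome 8 from 3681737 to 3694175, fell by 4.43 ± 0.53, at 6.26 ± 1.70 against 141.5 ± 13.1 CPM. Changes of genes are given on the log2 scale. In total 3138 of 10539 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1598 higher and 1540 lower in the ABC-like cells, and 1162 of them differed by at least 2-fold.

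Of the 10 ABC markers 9 were higher, also 9 when adjusted over the list alone. Among them Cd80, a costimulatory ligand, rose by 3.66, Lgals1, which encodes galectin-1, by 3.64, Ahnak by 3.11, Itgam, the gene of CD11b, by 2.65 ± 0.55 and Tbx21, the gene of T-bet on chromosome 11 from 97098071 to 97115331, by 1.28 ± 0.27. Of the 8 follicular markers 6 were lower, and 7 when adjusted over the list alone, with the complement inhibitor Cd55 at -2.81, Ighd at -2.54 and the chromatin organiser Satb1 at -2.43. Both lists served to name the clusters and are no independent evidence (camera adjusted p = 3.84e-13 and 1.76e-08). All 5 measured B1 cell markers were higher, also 5 when adjusted over the list alone, with the inhibitory receptor Ctla4 at 3.51, the repressor Zbtb32 at 3.32 and the integrin Itgb1 at 3.17 (camera adjusted p = 1.58e-10). The calls of these 3 lists held with an estimated correlation.

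Of 20 genes of the secretory pathway and unfolded protein response 17 rose and 1 fell, the same numbers when adjusted over the list alone. Edem1, which helps to clear misfolded proteins, stood at 1.94 and the chaperone Creld2 at 1.85. Of 11 plasmablast markers 8 rose, also 8 when adjusted over the list alone. Sdc1, the gene of CD138, stood at 2.93, Derl3 at 2.53 and Jchain, which joins secreted IgM and IgA, at 2.32. Camera gave these lists adjusted p = 8.87e-08 and 1.26e-05, and both calls were lost at adjusted p = 0.303 and 0.146 with an estimated correlation. Of 13 inhibitory receptors 6 rose and 0 fell, and 7 rose when adjusted over the list alone, including Pdcd1, the gene of PD-1, at 4.04, Sirpa at 2.16 and Lilrb4a at 2.04 (camera adjusted p = 0.0055; adjusted p = 0.191 with an estimated correlation).

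Of 17 immediate early genes of antigen receptor signalling 11 fell and 0 rose, and 13 fell when adjusted over the list alone, among them the transcription factors Egr3 at -1.74, Nr4a1 at -1.55 and Myc at -0.93 (camera adjusted p = 0.0055; adjusted p = 0.146 with an estimated correlation). Of 17 receptor signalling genes 8 fell and 2 rose, and 9 fell and 2 rose when adjusted over the list alone, with the complement receptor Cr2 at -2.98 and the adaptor Bank1 at -0.87 among the falls and Cd81, a part of the CD19 complex, at 1.06 among the rises (camera adjusted p = 0.018; adjusted p = 0.379 with an estimated correlation). Of 6 memory markers 3 rose and 1 fell, also when adjusted over the list alone. Nt5e, the gene of CD73, stood at 3.07 and the chemokine receptor Ccr6 at -2.07 (camera adjusted p = 0.0164; adjusted p = 0.191 with an estimated correlation). Of 24 oxidative phosphorylation genes 11 rose and 0 fell, also 11 when adjusted over the list alone, the largest rise being Ndufa1 at 0.62 (camera adjusted p = 0.013; adjusted p = 0.647 with an estimated correlation).

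Outside the lists, the largest rises included Cdkn2a, which encodes cell cycle inhibitors, at 4.49 ± 0.23, with 87.9 ± 11.8 against 3.96 ± 0.512 CPM. Spon1 rose by 4.36, Fcer1g, the signalling chain of Fc receptors, by 4.29 ± 0.28, Fah, an enzyme of tyrosine breakdown, by 3.96, the membrane-binding Anxa2 by 3.52 and the actin-bundling Fscn1 by 3.45. Fas rose by 2.50 ± 0.15, and in this strain the gene is disrupted by an inserted retroelement. The largest falls included Pxk at -2.24, Sorl1 at -2.22, Cxcr5, the chemokine receptor that guides B cells into follicles, at -2.16, Serpinb1a at -2.15, Icosl, the ligand of the T cell receptor ICOS, at -2.15, Ffar2 at -2.09 and Pkib at -2.08. Pdcd1lg2 and Ighm, at -0.60 and 0.46, did not pass the test.

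Some markers of cells that the sort excludes were also higher in cluster 5. Cd3g, a chain of the T cell receptor complex on chromosome 9 from 44969572 to 44980431, showed the largest rise of the named genes above the abundance minimum, 5.44 ± 0.56, at 189.6 ± 74.8 against 4.84 ± 3.47 CPM. Of 7 T cell markers 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0307; adjusted p = 0.146 with an estimated correlation). Of 11 myeloid markers 4 rose, also 4 when adjusted over the list alone. S100a9 stood at 4.04 and S100a8 at 3.86 (camera adjusted p = 0.0744), and S100a9 stood at -0.70 without mouse 1. Of 5 dendritic markers 3 rose, also 3 when adjusted over the list alone. Cst3 stood at 2.55 (camera adjusted p = 0.0154; adjusted p = 0.199 with an estimated correlation). Of 4 erythroid markers 2 rose, and 4 when adjusted over the list alone, and Hbb-bt, at 4.95 ± 1.83, varied between mice by more than its mean (152.7 ± 252 CPM; camera adjusted p = 0.517). Cells of other lineages made up 4.23% of cluster 5 and 1.56% of cluster 2. Without such cells in any cluster, a check chosen after the data were seen, 2007 genes passed. That filter also took 81.5% of the cells of cluster 9, whose sums are part of the shared fit. The count of 2007 can therefore not be laid to cells of clusters 5 and 2 alone. Without clusters 6 and 9 in the fit 3460 genes passed, and 1910 and 1875 passed without mouse 1 and without mouse 2.

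**Figure D2:**
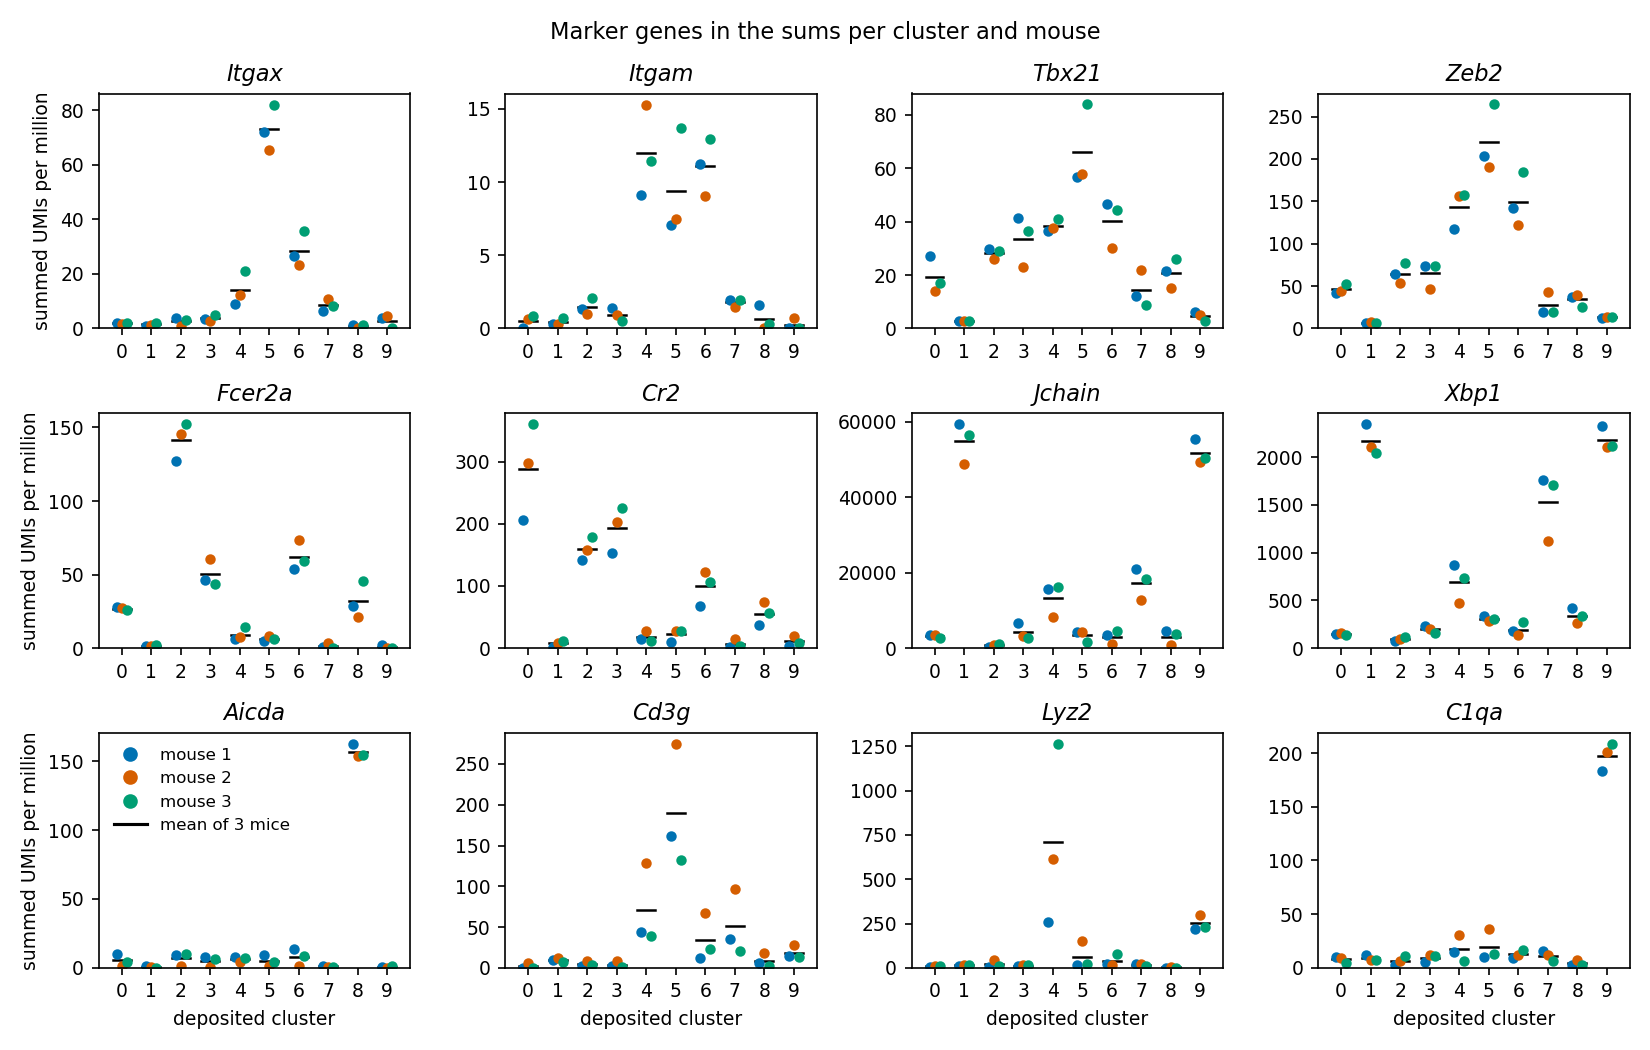
Level of 12 marker genes in CPM of the summed counts of each cluster and mouse, each gene on its own linear axis from 0; points are the 3 mice and lines their mean. Itgax was highest in cluster 5 at 73.2 CPM and stood at 14.2 CPM in cluster 4, while Cd3g reached 189.6 CPM in cluster 5.

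The second comparison set the ABC-like cells against the plasmablast-like cells of cluster 1, which secrete antibody. All 20 fixed genes of the secretory pathway were lower in the ABC-like cells, a call that held with an estimated correlation, and 10 of 11 MHC class II genes were higher, a call that was lost (adjusted p = 0.0595 with an estimated correlation). Zeb2, a transcription factor of ABCs, rose by 3.87 ± 0.26, at 219.7 ± 39.2 against 6.63 ± 0.332 CPM, and Ciita, the master regulator of MHC class II, by 3.46 ± 0.26, at 155.4 against 6.25 CPM. Jchain fell by 5.12 ± 0.61, at 3412 ± 1453 against 54850 ± 5495 CPM, and Xbp1, the transcription factor of the secretory program, by 3.98 ± 0.25. In edgeR's test 5771 of 10539 genes passed an adjusted p of 0.05, 3294 higher and 2477 lower in cluster 5, and 2909 differed by at least 2-fold.

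All 20 secretory pathway genes fell, also 20 when adjusted over the list alone. Edem2 stood at -3.53, Edem1 at -3.38 and Creld2 at -3.28. All 11 plasmablast markers fell too, also 11 when adjusted over the list alone, with the survival receptor Tnfrsf17 at -5.36, Fkbp11 at -4.40, Slpi at -4.25 and Sdc1 at -4.06. Camera gave adjusted p = 1.19e-17 and 1.82e-08, and the calls held with an estimated correlation; the plasmablast list served to name cluster 1. Of 11 MHC class II genes 10 rose and 1 fell, also when adjusted over the list alone. H2-Oa stood at 3.33, H2-DMb2 at 3.23 and H2-Ob at 2.74 (camera adjusted p = 8.88e-07; adjusted p = 0.0595 with an estimated correlation). Of 11 nucleic acid sensing genes 10 rose and 1 fell, also when adjusted over the list alone, including the endosomal receptors Tlr9 at 3.90 and Tlr7 at 2.61 (camera adjusted p = 2.06e-04, held with an estimated correlation). Of 13 inhibitory receptors 11 rose and 0 fell, also when adjusted over the list alone. Cd72 stood at 3.91, Fcrl5 at 3.83, Pdcd1 at 3.60 and Lilrb4a at 3.57 (camera adjusted p = 1.36e-05, held with an estimated correlation).

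Of 10 ABC markers 8 rose, also 8 when adjusted over the list alone. Itgax stood at 4.52, Tbx21 at 3.36 and Itgam at 3.28 (camera adjusted p = 7.71e-06, held with an estimated correlation). All 6 memory markers rose, also 6 when adjusted over the list alone. Nt5e stood at 4.77 and Cd38 at 2.88. Of 10 costimulation genes 9 rose and 1 fell, also when adjusted over the list alone. Cd86 stood at 3.07 and Cd40 at 2.60. Camera gave these lists adjusted p = 7.71e-06 and 7.76e-04, held with an estimated correlation. Of 17 receptor signalling genes 13 rose and 2 fell, also when adjusted over the list alone. Pik3ap1 stood at 2.84, Prkcb at 2.61 and Blk at 2.38 (camera adjusted p = 2.55e-05, held with an estimated correlation). Of 10 cytokine genes 9 rose, and 10 when adjusted over the list alone. Csf1 stood at 3.78 and Tnf at 2.96 (camera adjusted p = 2.28e-04; adjusted p = 0.0614 with an estimated correlation). Other large rises were Rgs1, which dampens chemokine signalling, at 3.81, the homing receptor Ccr7 at 3.70, Fam3c at 3.57, Il9r at 3.46, Cd22 at 3.42, Hck at 3.40 and Ncf1 at 3.40. Other large falls were Pycr1, an enzyme of proline synthesis, at -4.65, Oosp1 at -4.37, Rgcc at -4.13, Trp53inp1 at -4.02 and Plpp5 at -3.91.

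Of 24 oxidative phosphorylation genes 16 fell and 0 rose, and 17 fell and 1 rose when adjusted over the list alone. Ndufa1 stood at -2.18 and Uqcrq at -1.44 (camera adjusted p = 3.68e-04; adjusted p = 0.325 with an estimated correlation), and with library size alone Ndufs6 and Cycs turned from -1.13 and -0.96 to 0.04 and 0.21. Of 205 immunoglobulin variable segments 183 were lower in cluster 5 and 0 higher, at a median of -5.14. Some markers of other lineages differed as well. Of 7 T cell markers 6 rose, also 6 when adjusted over the list alone, and Cd3g stood at 3.02 (camera adjusted p = 0.0836). Of 11 myeloid markers 4 rose, also 4 when adjusted over the list alone. S100a9 stood at 4.85 (camera adjusted p = 0.774), while cells of other lineages made up 7.11% of cluster 1 and 4.23% of cluster 5. Of 8 genes of the list of dissociation stress, which respond to cell handling, 6 fell and 1 rose, also when adjusted over the list alone. Hspb1 stood at -3.56, Fos at -2.46, Jun at -2.29 and Dnajb1 at -1.10, or 0.07 with library size alone (camera adjusted p = 0.00218, held with an estimated correlation). Fas, Cd44, Cr2 and Fcer2a, at 0.12, -0.17, 0.43 and 0.85, did not pass the test, but with library size alone Cd44 stood at 1.00 and passed (edgeR adjusted p = 6.84e-05). Immunoglobulin genes took 52.7% of the UMIs of cluster 1 and 5.48% of those of cluster 5, so the scaling matters here: with library size alone the median change of all genes moved from 0.14 to 1.30, and 9109 genes passed, 8401 higher and 708 lower.

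The third comparison set the ABC-like cells against cluster 8, the germinal-centre-like and proliferating cells. The fixed proliferation genes were lower in the ABC-like cells and those of migration and adhesion higher, and both calls held with an estimated correlation. Most germinal centre markers were also lower, and most MHC class II and nucleic acid sensing genes higher, but the calls of these lists were lost, at adjusted p = 0.0701, 0.0839 and 0.0839 with an estimated correlation. Mef2b, a transcription factor of germinal centre cells, fell by 4.79 ± 0.51, at 12.7 ± 5.84 against 355.4 ± 47.4 CPM, and Hmces, which shields damaged DNA sites, by 4.67 ± 0.23. Itgax rose by 6.19 ± 0.56, with 568 UMIs in cluster 5 and 8 in cluster 8. In edgeR's test 4921 of 10539 genes passed an adjusted p of 0.05, 2732 higher and 2189 lower in cluster 5, and 2123 differed by at least 2-fold.

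All 15 proliferation genes fell, also 15 when adjusted over the list alone. Cdk1 stood at -4.47, Cenpf at -4.37, Rrm2 at -3.95 and Ube2c at -3.91, and outside the list Ccna2 at -3.99, Hist1h2ap at -3.92, Pclaf at -3.86, Aurkb at -3.81 and Hist1h1b at -3.63 (camera adjusted p = 4.48e-20, held with an estimated correlation). Of 9 germinal centre markers 8 fell and 1 rose, also when adjusted over the list alone. Aicda, the enzyme of somatic mutation and class switching, stood at -5.38 ± 0.64 and Gcsam at -5.13 (camera adjusted p = 4.53e-05; adjusted p = 0.0701 with an estimated correlation). These lists served to describe cluster 8. All 10 ABC markers rose, also 10 when adjusted over the list alone. Cd80 stood at 3.88, Itgam at 3.70 and Ahnak at 3.40 (camera adjusted p = 3.27e-08, held with an estimated correlation), and Tbx21 stood at 1.77. Of 17 migration and adhesion genes 12 rose and 1 fell, also when adjusted over the list alone. Itgb1 stood at 2.37, Itgb7 at 2.34 and Ccr7 at 2.03 (camera adjusted p = 9.41e-06, held with an estimated correlation). Other large rises were Fcer1g at 4.67, Tyrobp, an adaptor of activating receptors, at 3.71, Lgals3 at 3.69, Spon1 at 3.61 and Bhlhe41 at 3.11.

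All 11 MHC class II genes rose, also 11 when adjusted over the list alone. Ciita stood at 1.44, H2-Eb1 at 1.37 and H2-DMb1 at 1.35 (camera adjusted p = 6.76e-06; adjusted p = 0.0839 with an estimated correlation). Of 11 nucleic acid sensing genes 8 rose and 0 fell, also when adjusted over the list alone. Tlr7 stood at 2.66 and Tlr9 at 1.70. Of 13 inhibitory receptors 11 rose and 0 fell, and 12 rose when adjusted over the list alone. Lilrb4a stood at 4.54 and Pirb at 3.00. Camera gave these lists adjusted p = 0.00162 and 1.76e-04, and adjusted p = 0.0839 for both with an estimated correlation. Of 17 immediate early genes 12 rose and 0 fell, also when adjusted over the list alone. Egr2 stood at 1.81 and Jun at 1.26 (camera adjusted p = 0.00248; adjusted p = 0.0839 with an estimated correlation). Of 15 glycolysis genes 9 fell, also 9 when adjusted over the list alone. Ldha stood at -1.29 and Pgk1 at -1.03. Of 24 oxidative phosphorylation genes 17 fell, also 17 when adjusted over the list alone. Atp5b stood at -1.07. Mitochondrial genes went the other way, with 11 of 13 higher and 0 lower in cluster 5, at a median of 0.46. Camera gave glycolysis adjusted p = 0.00215 (adjusted p = 0.213 with an estimated correlation) and oxidative phosphorylation adjusted p = 2.15e-04 (adjusted p = 0.275 with an estimated correlation).

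Some markers of myeloid and T cells were also higher. Lyz2, a lysozyme of myeloid cells, stood 5.30 ± 0.90 higher, at 62.4 ± 75.8 against 2.04 ± 2.15 CPM. Of 11 myeloid markers 9 rose, and 10 when adjusted over the list alone (camera adjusted p = 0.00699; adjusted p = 0.196 with an estimated correlation). Of 7 T cell markers 4 rose, also 4 when adjusted over the list alone, and Cd3g stood at 4.95 (camera adjusted p = 0.137). Cluster 8 held 51 cells in mouse 2, and the summed counts ranged from 664187 to 4010084 UMIs. With library size alone the median change of all genes moved from 0.12 to -0.01, and 2151 genes were higher and 2677 lower.

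The fourth comparison asked how cluster 5 differed from cluster 4, the other cluster with ABC markers, and was chosen after the markers had been seen. Cluster 5 held more Itgax RNA, at 73.2 ± 8.32 against 14.2 ± 6.17 CPM, a rise of 2.37 ± 0.195 (SE, n = 3 mice; edgeR adjusted p = 0.0120), while Itgam, Tbx21 and Fas, at -0.50, 0.68 and 0.48, did not pass the test. In all 53 of 9466 genes passed an adjusted p of 0.05 in edgeR's test on the 6 sums of these clusters, 12 higher and 41 lower in cluster 5, of which 42 differed by at least 2-fold. Of 11 plasmablast markers 4 fell, and 11 when adjusted over the list alone. Tnfrsf17 stood at -2.87, Slpi, a protease inhibitor, at -1.40, Xbp1 at -1.20 and Ly6c2 at -0.67. Of 20 secretory pathway genes 1 fell, Xbp1, and 17 when adjusted over the list alone. Camera gave these lists adjusted p = 2.85e-11 and 4.88e-08, and both calls were lost at adjusted p = 0.423 and 0.486 with an estimated correlation. Of 143 immunoglobulin variable segments 11 were lower and 0 higher in cluster 5, at a median of -1.53, and immunoglobulin genes took 13.8% of the UMIs of cluster 4 and 5.48% of those of cluster 5. Of 15 proliferation genes 2 fell when adjusted over the list alone, and none passed over all genes in edgeR's test (camera adjusted p = 0.00218; adjusted p = 0.486 with an estimated correlation).

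Of 10 ABC markers Itgax alone rose, and 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0184; adjusted p = 0.439 with an estimated correlation). Other rises were the transcription factor Msc at 2.10 ± 0.125, Bcl2a1a, a survival gene of the Bcl2 family, at 1.29, the complement regulator Cfp at 1.27, Gatm at 1.06, Jakmip1 at 0.96, Gng3 at 0.91, Il4i1 at 0.80 and Fah at 0.79. Other falls were Ifitm3 at -3.03 ± 0.213, H1f0 at -1.43, Eaf2 at -1.33, Tyrobp at -1.14, Tmem176b at -1.12 and Fos at -0.56. Markers of other lineages went both ways. The granulocyte genes Elane, Ctsg and Prtn3 had 1, 3 and 4 UMIs in cluster 5 and 752, 591 and 1078 in cluster 4, and all passed as lower. Of 9 myeloid markers 2 were lower when adjusted over the list alone (camera adjusted p = 0.00218). Of 5 dendritic markers 4 were higher when adjusted over the list alone (camera adjusted p = 3.65e-05), and none of either list passed over all genes in edgeR's test. Of 5 T cell markers 1 rose, Cd3g at 1.49 ± 0.14, and 3 when adjusted over the list alone (camera adjusted p = 0.00218). All of these 3 calls were lost, each at adjusted p = 0.423 with an estimated correlation. Cells counted as other lineages made up 6.77% of cluster 4 and 4.23% of cluster 5, and without them 28 genes passed, where Ifitm3 stood at -1.51 and Tyrobp at 0.06 and neither passed. The count was 80, 217 and 95 without mice 1, 2 and 3, 87 without candidate doublets, 3 without the mouse block and 303 with all 10 clusters in the fit, 29 of them among the 53. Without mouse 1 the calls of Gatm, Jakmip1, Gng3, Fah, Eaf2, Xbp1, Tmem176b, Tnfrsf17, Fos and Ly6c2 were lost, without mouse 2 those of Gng3 and Fos, and without mouse 3 those of Gng3, Il4i1, Eaf2, Xbp1, Tmem176b and Fos. DESeq2 called 134 genes higher and 202 lower, library size alone gave 43 and 78, and leaving out immunoglobulin genes gave 208 and 321.

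The fifth comparison defined the cells by surface protein alone, so that no transcript entered the grouping. The gate for CD11c and CD11b held 346, 480 and 219 cells of mice 1, 2 and 3, of which 45.0% came from cluster 5, 34.4% from cluster 4 and 11.8% from cluster 6, and the CD23 gate held 577, 1059 and 1609 cells, of which 58.6% came from cluster 2. The transcripts of the gated proteins followed the gate: Itgax rose by 4.91 ± 0.22, at 47.3 ± 9.65 against 1.77 ± 0.693 CPM, Itgam by 3.57 ± 0.29, and Fcer2a fell by 3.09 ± 0.16. Of 10057 genes 1664 passed an adjusted p of 0.05 in edgeR's test, 1116 higher and 548 lower in the CD11c and CD11b gate, and 791 differed by at least 2-fold.

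Of 10 ABC markers 9 rose, and 10 when adjusted over the list alone. Ahnak stood at 3.09, Cd80 at 3.09, Zeb2 at 2.01 and Tbx21 at 1.17. All 5 B1 markers rose, also 5 when adjusted over the list alone. Ctla4 stood at 3.10, Zbtb32 at 2.94, Itgb1 at 2.93 and Bhlhe41 at 2.72. Of 20 secretory pathway genes 17 rose, also 17 when adjusted over the list alone. Edem1 stood at 1.69 and Creld2 at 1.64. Of 11 plasmablast markers 9 rose, and 10 when adjusted over the list alone. Ly6c2 stood at 2.32 and Sdc1 at 2.10. Of 8 follicular markers 4 fell, also 4 when adjusted over the list alone. Satb1 stood at -1.85, Ighd at -1.76 and Cd55 at -1.71. Of 8 germinal centre markers 4 fell and 1 rose, and 6 and 1 when adjusted over the list alone. Gcsam stood at -2.44 and Aicda at -1.94. Camera gave adjusted p = 2.06e-13, 1.25e-08, 1.25e-08, 1.98e-08, 1.07e-04 and 0.0477 for these 6 lists. All of these calls were lost with an estimated correlation, at adjusted p = 0.603, or 0.648 for the germinal centre list. Other rises were Fcer1g at 3.76, Cdkn2a at 3.22, Fah at 2.72 and Cd44, an adhesion receptor, at 1.98, and other falls were Cnn3 at -2.58, Cr2 at -2.40, Rapgef4 at -2.28, Tmem108 at -2.18, Ell3 at -1.94, Pkib at -1.85, Gch1 at -1.81 and Ccr6 at -1.79.

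Of 10 myeloid markers 8 rose in the gate, and 10 when adjusted over the list alone. Lyz2 stood at 4.04 ± 0.61, S100a8 at 4.02 and Adgre1 at 3.94. All 3 erythroid markers rose, also 3 when adjusted over the list alone. Camera gave the myeloid list adjusted p = 2.57e-08 and the erythroid list adjusted p = 0.0104, and adjusted p = 0.603 for both with an estimated correlation. Prss34 had 1486 UMIs in the CD11c and CD11b gate and 1 in the CD23 gate, and Cd3g rose by 4.74 ± 0.27. In 10 simulated data sets with this comparison's spread, 9.23% to 21.6% of edgeR's calls at 0.05 were false, so adjusted p-values were too small there. At 0.01, 4.82% to 14.7% of simulated calls were false, and 606 genes of the real data passed. Both simulated groups had the means of the CD23 gate, and far fewer genes differed than the 1664 called. The false share depends on that number and cannot be carried over, but the real adjusted p-values may be too small as well. Without mouse 1 and without mouse 3 the count was 585 and 1086. Groups at the top and bottom 10 percent of cells by the mean of the CD11c and CD11b ratios gave 948. CD23 did not enter these groups, so their low cells are not those of the CD23 gate and the comparison is a different one. There Sdc1, Xbp1 and Edem1 stood at -0.47, -0.32 and -0.03. With library size alone the median change moved from -0.03 to -0.18, with 890 genes higher and 1377 lower.

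Surface proteins were compared between each cluster and cluster 2 as centred log ratios, which are relative, so that a rise of 1 protein lowers the others. On cluster 5 CD11c was 1.95 ± 0.080 higher (SE, n = 3 mice), CD11b 1.35 ± 0.092, the ectoenzyme CD73 1.31 and CD44 1.19, while CD23 was lower, at -3.07 ± 0.118, as were the complement receptor CD21 at -2.38 and IgM at -0.81. CD80 was 0.17 higher (limma adjusted p = 0.00243), but -0.06 on the scale of log2 counts per 1000. CD138 and CD273, at 0.23 and 0.05, did not pass (limma adjusted p = 0.0548 and 0.397). Cluster 4 carried CD11b at 1.76 above cluster 2, but CD11c at 0.27. On this cluster CD73 stood at 1.30, CD21 at -2.33 and CD23 at -2.95. On cluster 6 the differences were smaller for CD21 and CD23, and CD11b stood at 1.54, CD11c at 0.45, CD21 at -0.55 and CD23 at -1.17. Cluster 1 carried CD138, the plasma cell proteoglycan, at 2.68 and CD44 at 1.84, and cluster 0 carried IgM at 1.04 and CD21 at 0.64. Of the 90 differences 75 passed an adjusted p of 0.05 in limma's test, 49 higher and 26 lower, and with log2 counts per 1000 63 passed, 29 higher and 34 lower.

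**Figure D3:**
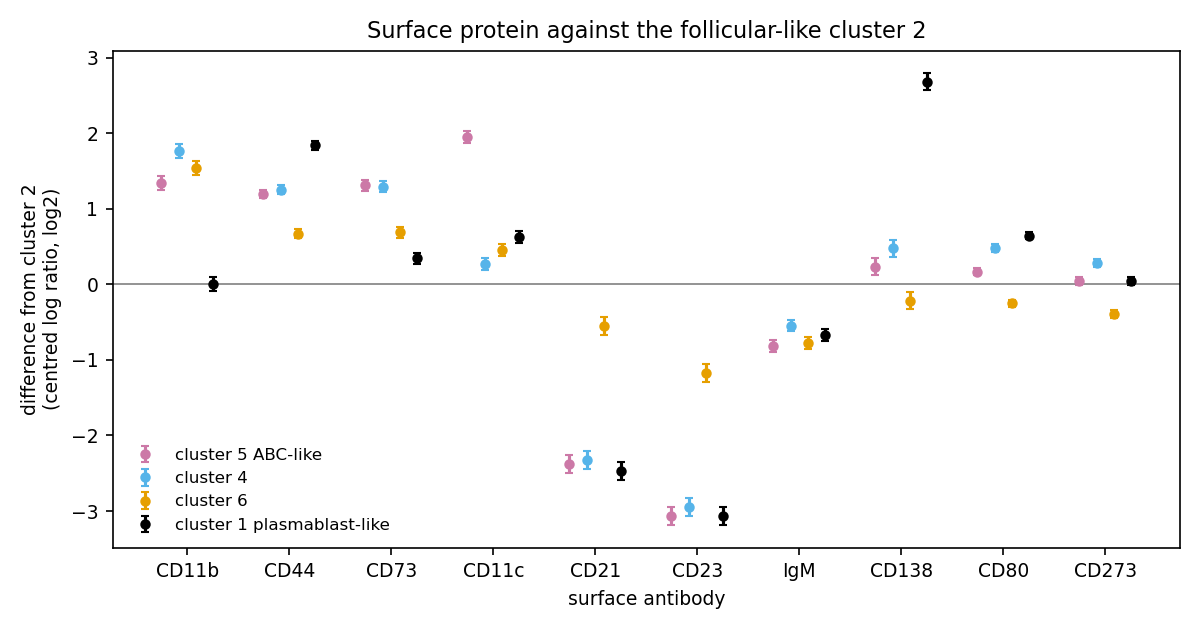
Difference of each surface protein between clusters 5, 4, 6 and 1 and cluster 2, in centred log ratio (log2) units; points are differences over 3 mice and bars their standard errors. CD11c stood at 1.95 on cluster 5 and at 0.27 on cluster 4, while CD11b stood at 1.35 and 1.76.

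Receptor chains gave the isotype and clone of a cell. Class-switched isotypes made up 57.7% ± 9.01 of cells with 1 heavy chain in cluster 5 and 11.7% ± 0.847 in cluster 2 (SD, n = 3 mice), a difference of 46.0 points, higher in 3 of 3 mice (exact sign-flip p = 0.25, the smallest possible with 3 mice). The share was 86.0% in cluster 1, 60.9% in cluster 4, 47.8% in cluster 8, 41.6% in cluster 6 and 9.98% in cluster 0. In cluster 5 IgM made up 39.5% ± 8.51, IGHG2C 22.2% ± 8.45, IGHG3 18.4% ± 13.6, IGHG2B 9.38% ± 11.3 and IGHG1 3.61% ± 2.21. Single mice weighed on these shares: without mouse 1 IGHG3 made up 10.6%, and without mouse 2 IGHG2B made up 2.85% and IGHG1 2.36%. In cluster 1 IGHG2C made up 32.3% ± 13.1 and IGHG1 13.6%. Isotype and V gene names are those of the reference the authors' contigs were named from, not of the strain's own alleles.

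Cells in clones of at least 2 cells, with clone mates counted in any cluster, made up 54.2% ± 11.3 of the paired cells of cluster 5 and 3.78% ± 1.83 of those of cluster 2. The difference was 50.4 points, higher in 3 of 3 mice (exact sign-flip p = 0.25). With equal numbers of cells drawn it was 41.0 points, at 42.3% against 1.30%. That draw counted mates only among the drawn cells of the same cluster, so the 2 differences vary in this measure as well as in cell number. In all 5213 cells with paired chains fell into 3542 clones, of which 290 held at least 2 cells and 215 of these reached more than 1 cluster. The largest, in mouse 2, held 161 cells with IGHV1-43 and IGHJ4, all class-switched, of which 115 lay in cluster 1, 15 in cluster 4 and 7 in cluster 5. Cluster 5 shared 57 clones with cluster 1, where permuted labels gave a mean of 93.7 and a range of 73 to 111, 47 with cluster 4 (53.3, 41 to 70), 11 with cluster 8 (13.6, 6 to 22), or 20 where clones needed only 85 percent identical CDR3, and 10 with cluster 2 (range 4 to 17). Cells are not replicates in these counts, and the share of cells with paired chains was 40.6% in cluster 5, 62.5% in cluster 1 and 26.7% in cluster 2. The median heavy chain held 1689 UMIs in cluster 1, 12 in cluster 5 and 8 in cluster 2. With at least 5 UMIs per chain, clusters 1 and 5 shared 54 clones, and the expanded difference was 50.4 points. That minimum lies under these medians, and free receptor RNA as a source of shared clones was not tested.

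Among 26 heavy V genes, counted over 255 clones of cluster 5 and 629 of cluster 2, IGHV1-69 was more frequent in cluster 5, at 5.13% ± 1.97 against 1.46% ± 0.759 of clones, and IGHV1-53 was less frequent, at 1.18% ± 0.037 against 4.27% ± 1.54 (edgeR adjusted p = 0.0321 for both). These rest on 13 and 11 clones and on 3 and 24 clones, the test recovered 0 of 9 simulated 4-fold changes, and 0 V genes passed edgeR's test in each of the 6 alternatives, in which 0 to 6 had an unadjusted p under 0.05. The mean heavy CDR3 length was 14.2 ± 0.26 amino acids in cluster 5 and 14.2 ± 0.11 in cluster 2, a difference of 0.072, higher in 2 of 3 mice (exact sign-flip p = 0.75). It was -0.0615 without mouse 1, -0.161 in unswitched clones alone and 0.317 with cells in place of clones.

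**Figure D4:**
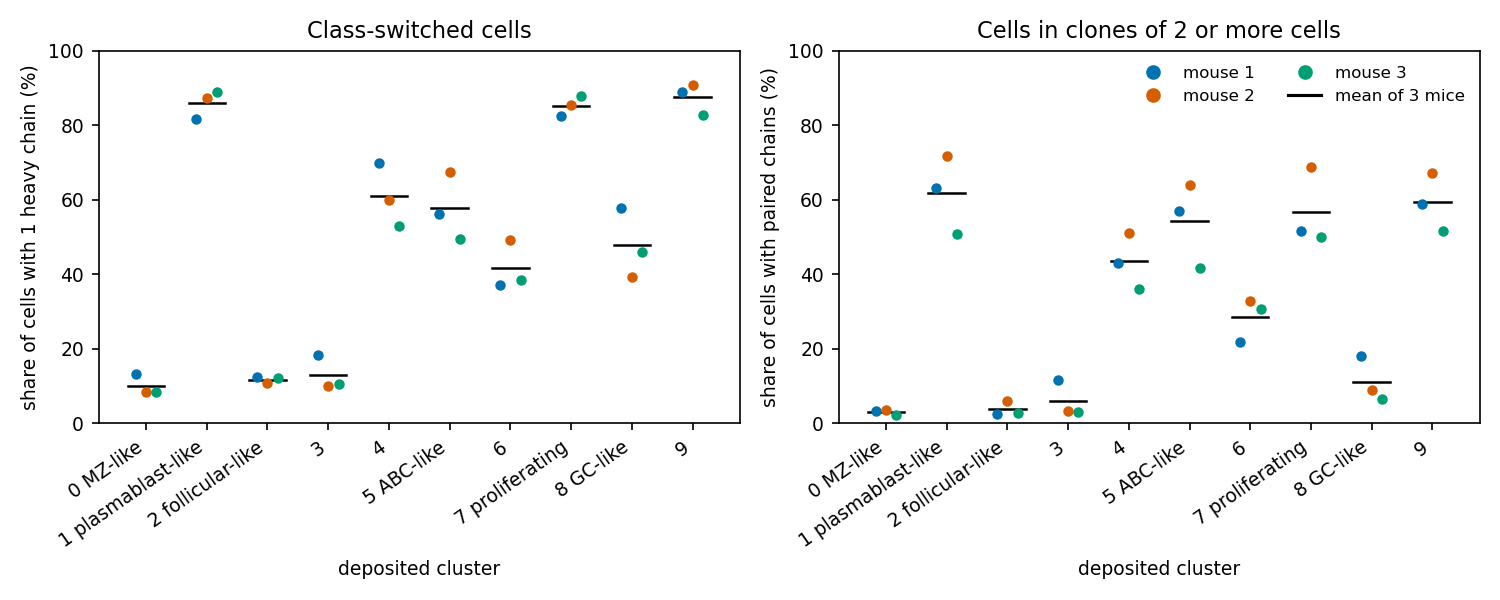
Percent of cells with a class-switched heavy chain and percent of paired cells in clones of at least 2 cells, per cluster; points are the 3 mice and lines their mean. Cluster 5 reached 57.7% and 54.2%, and cluster 2 11.7% and 3.78%.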

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

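The tests of stuck cells, of free RNA in both clusters and of T cells were chosen after the results had been seen, while those of chance doublets and of a few high cells were written before their values were known. Mice were in a group of 3, too few for a search for a mouse far from the others. No barcode of the 2 sets that follow entered a comparison between clusters or gates. Outside the table of analysed cells, 1417 barcodes carried the hashtags of 2 mice, which any pooled droplet run holds; they served only to estimate doublets. Receptor chains were also found for 587 barcodes that are absent from the expression matrix.

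Cluster 6 held RNA and protein of both the ABC-like and the follicular-like cells, with a median of 10818 UMIs per cell. The barcodes with 2 hashtags imply 748.8 doublets of cells of the same mouse, and chance doublets would make up 14.2% of cluster 6 (upper bound 16.9% for counting error) from a classifier that put 85.7% of held-out cells in their own cluster, or 13.3% from a first classifier that was less accurate, at 58.3%, which argues against chance doublets as the whole cause and leaves them as a likely part. Cells of 1 mouse that stuck together before pooling stay open: 28.4% of cluster 6 cells of matched depth had at least 2 light chains (95% interval 22.6 to 34.7), against 26.2% in cluster 2, 18.6% in cluster 5 and 32.1% of 2-hashtag barcodes assigned to cluster 6 (20.3 to 46.0). Free RNA spread evenly over the droplets would make up no more of cluster 6 than of cluster 5, whose cells are less deep at 6435 UMIs. The median ratio of the follicular list was 3.14, 3.21 and 1.84 in mice 1, 2 and 3, with Fcer2a at 9.91 and Ighd at 4.56. CD23 protein stood at 0.04 ± 0.33 against -1.86 ± 0.21. These values argue against evenly spread free RNA as the source. Cluster 6 was singled out by markers of this same list, so a ratio above 1 was favoured by that choice. The bound of 1 was set after the values were known, when mouse 3 had not passed a first bound of 2. The test therefore cannot decide on free RNA that differs between droplets. No biological explanation was tested because there was 1 condition.

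Cluster 9 held plasmablast RNA together with complement RNA of macrophages, although the sort required CD19. Chance doublets of a plasmablast and a macrophage would make up 0.712% of its cells, or 6.57% if every other barcode with this RNA were a macrophage, which argues against them as its cause. Free RNA of macrophages, if spread evenly over the droplets, would reach clusters 9 and 1 alike. C1qa, C1qb and C1qc stood at 198, 193 and 156 CPM in cluster 9 and at 8.93, 12.1 and 10.5 CPM in cluster 1, and the lowest ratio of the 3 mice was 12.9. Further macrophage genes stood apart as well, with Ccl8 at 134 against 5.49 CPM and Hmox1 at 73.9 against 10.5 CPM. Cluster 9 was singled out by its macrophage genes, and the clusters appear to have been drawn from the same RNA, so a high ratio was favoured in advance. The values therefore cannot decide on free RNA that differs between droplets. Cells that adhered before the droplets were made, or that took up others, may explain the cluster and were not tested, nor was a biological explanation.

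Cd3g RNA was raised in cluster 5, although the sort excluded cells with a T cell receptor beta chain: 52.6% of its cells carried a UMI, against 35.8%, 27.4% and 25.2% in clusters 7, 4 and 6 and 1.51% in cluster 2, at medians of 6435 UMIs per cell in cluster 5 and 4559 in cluster 2. T cells with that chain would bring the constant chains of their receptor. Trac and Trbc2 together came to at most 0.769% of the Cd3g level in any mouse. The sort had removed cells with the beta chain, so this low value was favoured in advance and says little of other T cells. Cd3e and Cd3d stood at 6.5 and 2.58 CPM beside 189.6 for Cd3g, which argues against T cells as the source of most of the Cd3g RNA. A small number of T cells stays open, since Cd3e, Cd3d, Cd8a, Cd4 and Thy1 stood at 0.56, 0.58, 0.12, 0.13 and 0.2 CPM in cluster 2 and Cd8a, Cd4 and Thy1 at 8.55, 1.67 and 1.77 CPM in cluster 5. A few cells with high counts met their prediction narrowly, since 113 cells with at least 5 UMIs held 51.1% of the Cd3g UMIs of the cluster, but 35.6% in mouse 1, 56.4% in mouse 2 and 52.1% in mouse 3, and UMIs in 52.6% of cells argue against these few as the whole source. A candidate explanation is Cd3g transcription in some of these B cells, a hypothesis found in these data, and no biological explanation was tested.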

How the results depend on the processing

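The settings without other-lineage cells, without clusters 6 and 9, with all 10 clusters in the fit of cluster 5 against 4 and with at least 5 UMIs per chain were chosen after the data were seen. Of 5636 values of named genes and antibodies under other settings, 5225 kept direction and side of the threshold, 366 lost and 23 gained the call and 22 reversed. Most named genes were picked because they passed the main test, so this tally was favoured in advance and cannot stand for genes in general. V genes were not part of this tally, and the 2 that passed in the main test lost their calls in every alternative. Except where stated, the cause was not tested. Leaving out 1 mouse leaves 2 per cluster, and depth limits the calls of genes with few UMIs. The fits of the gates and of cluster 5 against 4 hold only the groups compared, so that alternative is the same fit there.

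The count of genes in cluster 5 against 2 was 1875 to 2324 with 1 mouse left out and 2007 without other-lineage cells. Against cluster 1 it was 4662 to 4804 and 9109 with library size alone, and against cluster 8 3700 to 3910. Against cluster 4 it was 53, and 80 to 217 with 1 mouse left out, 336 with DESeq2, 121 with library size alone, 529 without immunoglobulin genes, 87 without candidate doublets, 28 without other-lineage cells, 303 with all 10 clusters in the fit and 3 with no replicate block. For the gates it was 585 to 1510 with 1 mouse left out, and 948 with the 10 percent groups, whose low cells were not selected by CD23. The pairing by mouse comes from the animals. Gene lists past 0.05 numbered 12, 16, 17, 12 and 10 in the 5 comparisons with camera, 3, 10, 4, 0 and 0 with an estimated correlation, and 18, 26, 26, 2 and 9 with fry. Clones shared by clusters 5 and 8 numbered 20 at 85 percent identity, V genes 0 in each alternative in edgeR's test (0 to 6 at an unadjusted p under 0.05), and antibody differences past 0.05 68 to 70 with 1 mouse left out. The switched difference was 40.7 to 50.2 points and the expanded difference 46.6 to 56.2 with 1 mouse left out. The CDR3 difference was -0.0615 to 0.179 with 1 mouse left out and -0.161 in unswitched clones, and 0.317 with cells in place of clones.

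Genes that reversed were S100a9 in cluster 5 against 2 (-0.70 to 5.35 with 1 mouse left out, the lowest without mouse 1) and, against cluster 1 with library size alone, Cd44 (1.00), Dnajb1 (0.07), Cst3 (0.10), Ndufs6 (0.0392) and Cycs (0.21), with Fas at -0.0007 without clusters 6 and 9. Against cluster 4 they were Tyrobp (0.0595 without other-lineage cells), Pdcd1lg2 (-0.0087 without other-lineage cells, -0.076 to 0.3232 with 1 mouse left out) and Cr2 (-0.0085 without other-lineage cells, -0.3026 to 0.4904 with 1 mouse left out), the lowest of both without mouse 3. Between the gates it was Ccl3 (-0.80 without other-lineage cells). In the 10 percent groups, whose low cells were not selected by CD23, they were Sdc1 (-0.47), Tnfrsf17 (-0.49), Xbp1 (-0.32), Fut8 (-0.0655), Slpi (-0.63), Edem1 (-0.0273) and Edem2 (-0.17). With log2 counts per 1000, CD80 stood at -0.0591 and CD273 at -0.12 on cluster 5.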

Other observations

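The lists and clones described here were picked from the planned results after their values had been seen, and the splits of the gene counts, but not those of proteins and V genes, were added after the counts were known. Ligands, adhesion genes and cytokines differed in cluster 5 against cluster 2 without moving 1 way as lists. Of 10 costimulation genes 3 rose and 3 fell, the same when adjusted over the list alone, with the ligands Cd70 at 5.26 and Tnfsf9 at 3.27 and Icosl at -2.15 (camera adjusted p = 0.841). The median change of that list was -0.32 and its mean 0.70. Of 17 migration and adhesion genes 5 rose and 6 fell, and 6 and 6 when adjusted over the list alone, with Cd9 at 3.35 and Cxcr5 at -2.16 (camera adjusted p = 0.517). Of 10 cytokine genes 5 rose and 3 fell, and 6 and 3 when adjusted over the list alone, with the chemokine Cxcl10 at 2.83 and Tnfsf13b, which encodes the survival factor BAFF, at 2.78 (camera adjusted p = 0.234). Of 24 B cell transcription factors 8 rose and 9 fell, the same when adjusted over the list alone. Bhlhe41 stood at 2.93, Zeb2 at 1.81, Foxp1 at -1.81 and Bcl6 at -1.78 (camera adjusted p = 0.517). Of 20 genes of the type I interferon response 2 rose and 5 fell, the same when adjusted over the list alone. Bst2 stood at 1.92 and Ifi208 at -3.12 (camera adjusted p = 0.517). Of 11 nucleic acid sensing genes 2 rose and 1 fell, the same when adjusted over the list alone. Tlr7 stood at 0.91 and Ddx58 at -0.75 (camera adjusted p = 0.525). Of 13 immunoglobulin constant genes 9 rose and 1 fell at a median of 2.12. Of 94 ribosomal protein genes 5 rose and 28 fell at a median of -0.11, beside -0.06 for all genes.

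Against cluster 1, 19 of 24 B cell transcription factors rose and 3 fell, the same when adjusted over the list alone. Spib stood at 3.36 (camera adjusted p = 1.36e-05; adjusted p = 0.0536 with an estimated correlation). Of 17 migration and adhesion genes 10 rose and 2 fell, the same when adjusted over the list alone. Ccr7 stood at 3.70 and the selectin Sell at 3.12 (camera adjusted p = 0.00318, held with an estimated correlation). Against cluster 8, 10 of 17 genes of the interferon gamma response rose and 0 fell, the same when adjusted over the list alone, with the GTPases Iigp1 at 1.06 and Igtp at 0.76 (camera adjusted p = 0.0259; adjusted p = 0.405 with an estimated correlation). Of 15 apoptosis and survival genes 8 rose and 3 fell, and 9 and 3 when adjusted over the list alone. Bcl2 stood at 2.17 (camera adjusted p = 0.0319; adjusted p = 0.0839 with an estimated correlation).

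The largest clones of mice 1, 2 and 3 reached 8, 9 and 10 of the 10 clusters, while others among the 25 largest reached as few as 3. Each of these largest clones reached some of its clusters by 1 cell only. Free receptor RNA as a source of this spread was not tested. The second largest held 104 cells of mouse 3 with IGHV3-6 and IGHJ3, of which 61 lay in cluster 1 and 12 in cluster 5, and the third held 94 cells of mouse 1 with IGHV1-43 and IGHJ3, of which 45 lay in cluster 1 and 26 in cluster 5. Cluster 5 shared 37 clones with cluster 7 (permuted mean 44.1, range 31 to 58), 27 with cluster 9 (32.0, 23 to 44) and 22 with cluster 6 (20.5, 11 to 32). Its 57 clones shared with cluster 1 were fewer than in each of 1000 permutations. This was not particular to cluster 5, since the 83 clones shared by clusters 1 and 4 were also fewer than in each (permuted range 84 to 120).

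The 6 sums of a comparison can be split in 10 ways, too few for a share under 0.05. With the 6 sums alone and without the mouse block, 1 of the 10 splits, the real one, gave the most calls: 2935 genes against at most 0 in the other splits for cluster 5 against 2, 6176 against 0 for cluster 1, 4012 against 0 for cluster 8, 3 against 1 for cluster 4 and 1927 against 1 for the gates. For surface protein on cluster 5 the real split gave 7 antibodies and the highest other 0. For V genes all 10 splits gave 0 in edgeR's test, with 2 V genes at an unadjusted p under 0.05 in the real one. Every other split mixed sums of both groups, and the clusters, unlike the gates, appear to have been drawn from the same RNA and protein counts. The real split was therefore favoured in advance for genes and proteins, and these counts are no independent evidence.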
